A study of Rattus norvegicus with 12 samples.

How the data were processed

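Hippocampal RNA from 6 bHR and 6 bLR male rats was measured on 12 Illumina RatRef-12 arrays, 1 array per rat. Per the submitters' processing notes and design text, the authors extracted the average bead signal of each probe with limma 3.28.21, took log2 and quantile normalised the arrays with preprocessCore 1.34.0, and kept all arrays although 1 stood apart in principal components. The deposited table of intensity values holds the linear average signal of 22523 probes, positive and not normalised between arrays, with no detection p-values, control probes or chip identifiers. A second deposited table holds the authors' log2 values after quantile normalisation. Background correction is not given in the sources used here.

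The deposited intensities were transformed to log2 and quantile normalised over the 12 arrays, with all probes and arrays kept, and with no background correction, since none is described. The result differed from the authors' log2 table by at most 0.254 and by a median of 0.0004 per value, and each authors' column had a median of 6.66. Each probe was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the bred line as the only factor. P-values are two-sided and Benjamini-Hochberg adjusted over all 22523 probes, with a threshold of 0.05, and differences are bHR minus bLR on the log2 scale. Rat numbers in the labels are animal numbers that no pair of rats shares, so no pairing was used. Each rat is a separate animal.

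Gene names came from the deposited table and were updated through a table of gene names of the GRCr8 assembly. Of the 22523 probes, 16836 matched (10235 by symbol, 4960 by synonym and 1641 by gene identifier), 5531 kept the file's symbol, 39 had ambiguous symbols and 117 no symbol. Gene positions on this assembly were used only to find neighbouring genes, and probe positions and sequences were not used here. Where a gene had several probes (917 genes), lists used the probe with the highest mean signal. A probe was called above the median signal where a line's mean passed the median of all probes, which held for 11451 probes, since detection p-values were not used here.

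The samples, tests, lists, naming rule and most alternative settings were fixed before the data were examined. The rule named the 10 largest differences in each direction among called probes with 1 gene symbol and a mean signal above the median of all probes in at least 1 line, filled up by the lowest p where fewer were called, up to 3 members of each list past 0.05 when adjusted over the list alone, and all measured genes recalled from earlier work on these lines. A result for 1 gene that this rule names is not reported here. In all, 39 lists of cell type markers, neighbouring tissues, signalling pathways and metabolism, each with at least 5 measured genes, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 39 lists. They were also tested with an estimated correlation, with fry, and with an exact permutation of the list means over all 924 assignments of the 12 rats. The smallest two-sided p of such a test is 0.0022. A list of sex-linked genes had 1 measured member (log2 6.54 in bHR and 6.59 in bLR) and was not tested.

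The probe test was tested on simulated data for the 22523 probes, with the spread of each probe in the real arrays. At each size 50 probes were planted, all drawn from those above the median signal in a line. The test recovered 80% at a log2 difference of 0.5, 92% at 0.75, 98% at 1 and 100% at 1.5. There were 9 false among 197 calls, where called probes of the shifted list below count among the calls and not as false. A planted shift of 0.2 in a list of 33 genes was recovered, and 0 other lists were called. The simulated probes varied independently of each other, and no simulated array was dim or set apart. This result therefore does not bear on lists whose genes vary together, or on false calls from variation that probes share.

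Alternative settings fixed then were median centring of arrays, no scaling between arrays, normexp background correction with an offset of 50, the authors' values, filters on dim probes, a variance trend with robust estimation, array weights, leaving out each rat, other thresholds, and the mean of all probes of a gene. Added after seeing the data were the 9 brighter arrays alone, brightness as a block, and the mean log2 raw signal as a covariate. Arrays read 453 to 1038 units on average. The ratio of the 95th to the 5th percentile of signal was 31.1 to 33.1 on the 3 dimmest arrays and 52.4 to 67.2 on the other 9.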

Results

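Total RNA from the whole hippocampus of 12 male rats, each 14 days old, was hybridised to Illumina RatRef-12 BeadChips, which carry 1 oligonucleotide probe or a few for each gene. The rats came from lines selectively bred for their locomotor response to an unfamiliar environment: 6 were bred High Responders (bHR) and 6 were bred Low Responders (bLR), all of generation F15. Each rat gave 1 array, so n = 6 per line throughout, and this number limits the precision. Mean probe signal per array ran from 453 to 1038 units. The 3 dimmest arrays (453 to 488 units) were all bHR, replicates 27, 29 and 39, while the other 9 (3 bHR and 6 bLR) read 750 to 1038 units. The first principal component of the normalised values held 28.1% of the variance and set bHR replicate 27 apart from the other rats. This array also had the lowest mean correlation with the others, 0.987 against at least 0.992.

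The design asks which hippocampal transcripts differ between the lines at this age. *Gabarapl2*, an ATG8-family protein of autophagosomes, was 1.79-fold higher in bHR (log2 difference +0.84 ± 0.09, SE, n = 6 per line), *Fam111a*, a nuclear protease, was 3.08-fold higher (+1.62 ± 0.21), and *Adpgk*, the ADP-dependent glucokinase, was 1.53-fold higher (+0.61 ± 0.08). Lower in bHR were *Farp1*, an exchange factor that acts in dendrite and synapse formation (-0.57 ± 0.06), *Slco2b1*, an organic anion transporter (-0.57 ± 0.06), and *Fem1c*, a substrate receptor of ubiquitin ligases (-0.69 ± 0.09). *Rps9*, a protein of the small ribosomal subunit, was also lower (-3.55 ± 0.62), with 1 bHR rat at the bLR level. In all, 20 of 22523 probes, for 19 genes, passed limma at an adjusted p of 0.05, of which 7 were higher and 13 lower in bHR. At an unadjusted p under 0.05 there were 1355 probes, 721 higher and 634 lower, where chance alone gives 1126. The ranges of the lines did not overlap for 15 of the 20 called probes, and for 88 of all probes (0.391%, against 0.217% by chance).

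**Figure D1:**
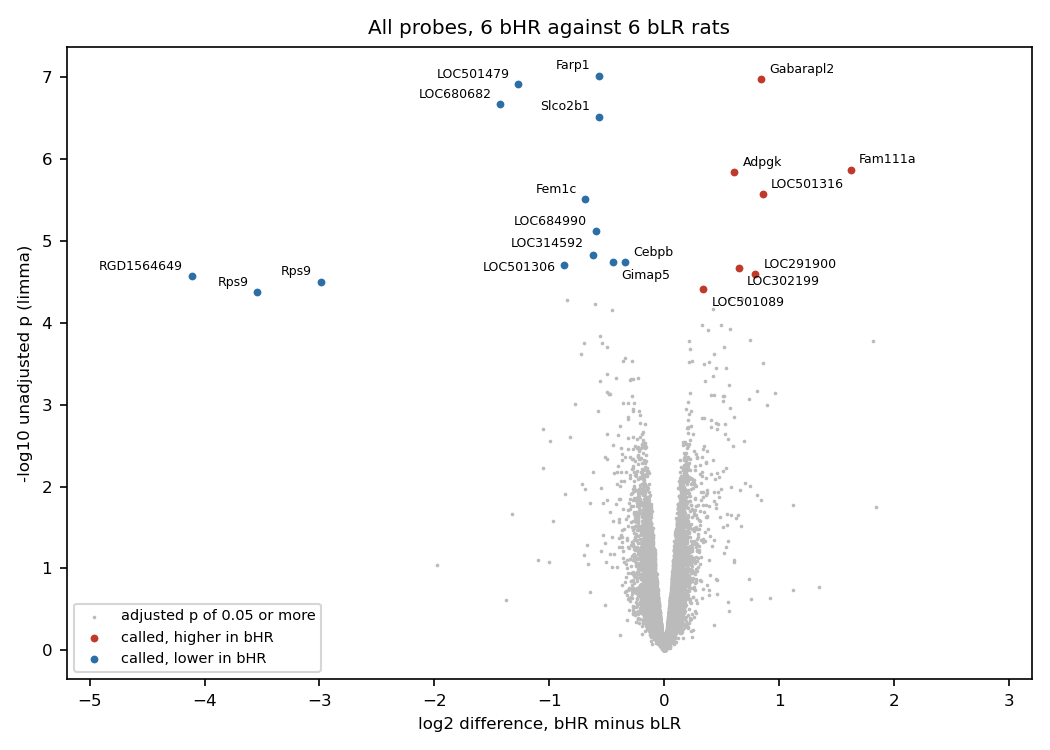
Each point is 1 of the 22523 probes, with the log2 difference (bHR minus bLR, 6 rats each) on the x axis and the negative log10 of the unadjusted limma p on the y axis. Coloured points are the 20 probes called at an adjusted p of 0.05, 7 higher (red) and 13 lower (blue) in bHR.

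Among the genes higher in bHR, *Gabarapl2* averaged a log2 signal of 10.91 ± 0.20 (SD, n = 6) in bHR and 10.07 ± 0.12 in bLR (limma adjusted p = 0.00091). For *Fam111a* the means were 8.65 ± 0.18 and 7.02 ± 0.58 (limma adjusted p = 0.0046), and for *Adpgk* 9.04 ± 0.12 and 8.43 ± 0.17 (limma adjusted p = 0.0046). Each of the 6 bHR rats lay above each bLR rat for these 3 genes. All 3 calls ended with other scaling: with median centring *Gabarapl2* gave +0.52 (limma adjusted p = 0.17), *Fam111a* +1.46 (0.083) and *Adpgk* +0.37 (0.17), and without scaling between arrays, where the median of all probes was -0.22, they gave +0.32 (0.16), +1.27 (0.092) and +0.17 (0.42). The other 4 called genes carry only provisional symbols: LOC501316 (+0.86), LOC291900 (+0.79), LOC302199 (+0.65) and LOC501089 (+0.34), with limma adjusted p from 0.0077 to 0.046. Of the 12 fits that leave out a rat, limma called LOC501316 in 12, LOC291900 in 2, LOC302199 in 1 and LOC501089 in 0. With median centring and without scaling, LOC501316 gave +0.66 and +0.46, LOC291900 +0.53 and +0.33, and LOC302199 +0.39 and +0.19, none of them called. The second LOC501089 probe gave +0.18 and was not called, and the first gave +0.01 with median centring and -0.19 without scaling. Next in rank, and not past the threshold, were *Hdac5*, a histone deacetylase (+0.56 ± 0.10, limma adjusted p = 0.052), *Faah*, the hydrolase of anandamide (+0.68 ± 0.12, limma adjusted p = 0.052), and LOC499295 (+0.43 ± 0.08, limma adjusted p = 0.061).

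On the lower side, *Farp1* averaged 8.08 ± 0.10 (SD, n = 6) in bHR and 8.65 ± 0.10 in bLR (limma adjusted p = 0.00091), while its second, dimmer probe gave -0.02. *Slco2b1* averaged 7.55 ± 0.12 and 8.12 ± 0.11 (limma adjusted p = 0.0014), and *Fem1c* 6.36 ± 0.23 and 7.05 ± 0.12 (limma adjusted p = 0.0079). For these 3 genes every bHR rat lay below every bLR rat. LOC680682 (-1.43) and LOC501479 (-1.27) lay near 6.3 in all 6 bHR rats, below the median of all probes (6.66), and between 7.56 and 8.06 in 5 bLR rats, with bLR replicate 42 at 6.83 and 6.91. The second probes of LOC501479 and LOC501306, below the median of all probes in both lines, gave -0.05 each. LOC501306 (-0.87), LOC314592 (-0.62) and LOC684990 (-0.60) were also called, with limma adjusted p of 0.032, 0.031 and 0.017, and were called in 3, 4 and 11 of the 12 fits that leave out a rat. With median centring and without scaling these 3 calls ended, at -1.15 and -1.35, -0.67 and -0.87, and -0.80 and -0.998, and without scaling so did that of *Farp1* (-0.99, limma adjusted p = 0.072), while *Slco2b1* kept its call (-0.96). The remaining called genes, *Gimap5*, a GTPase of lymphocytes (-0.45, limma adjusted p = 0.032), and *Cebpb*, a transcription factor (-0.34, limma adjusted p = 0.032), fell outside the rule for named genes and were chosen after their values were seen.

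The largest differences belonged to *Rps9* and the predicted gene RGD1564649, and they were steps between rats. *Rps9* averaged 8.97 ± 1.78 (SD, n = 6) in bHR and 12.51 ± 0.34 in bLR, with a limma adjusted p of 0.047, and its second probe gave -2.99 ± 0.50 (SE; limma adjusted p = 0.040). RGD1564649 averaged 7.67 ± 1.96 and 11.78 ± 0.46, a difference of -4.11 ± 0.68 (limma adjusted p = 0.036). In bHR replicate 41 both genes stood at the bLR level, 12.40 and 11.59, whereas the other 5 bHR rats read 7.42 to 9.20 for *Rps9* and 6.29 to 7.47 for RGD1564649. Without bHR replicate 41 the limma adjusted p was 1.7e-06 for *Rps9* and 1.7e-07 for RGD1564649. Of the 12 fits that leave out a rat, 1 called *Rps9* and 2 called RGD1564649. Within each line the brighter *Rps9* probe and the RGD1564649 probe ranked the 6 rats in the same order. They need not be separate differences, and whether they read 1 signal was not tested, since probe sequences were not used here.

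**Figure D2:**
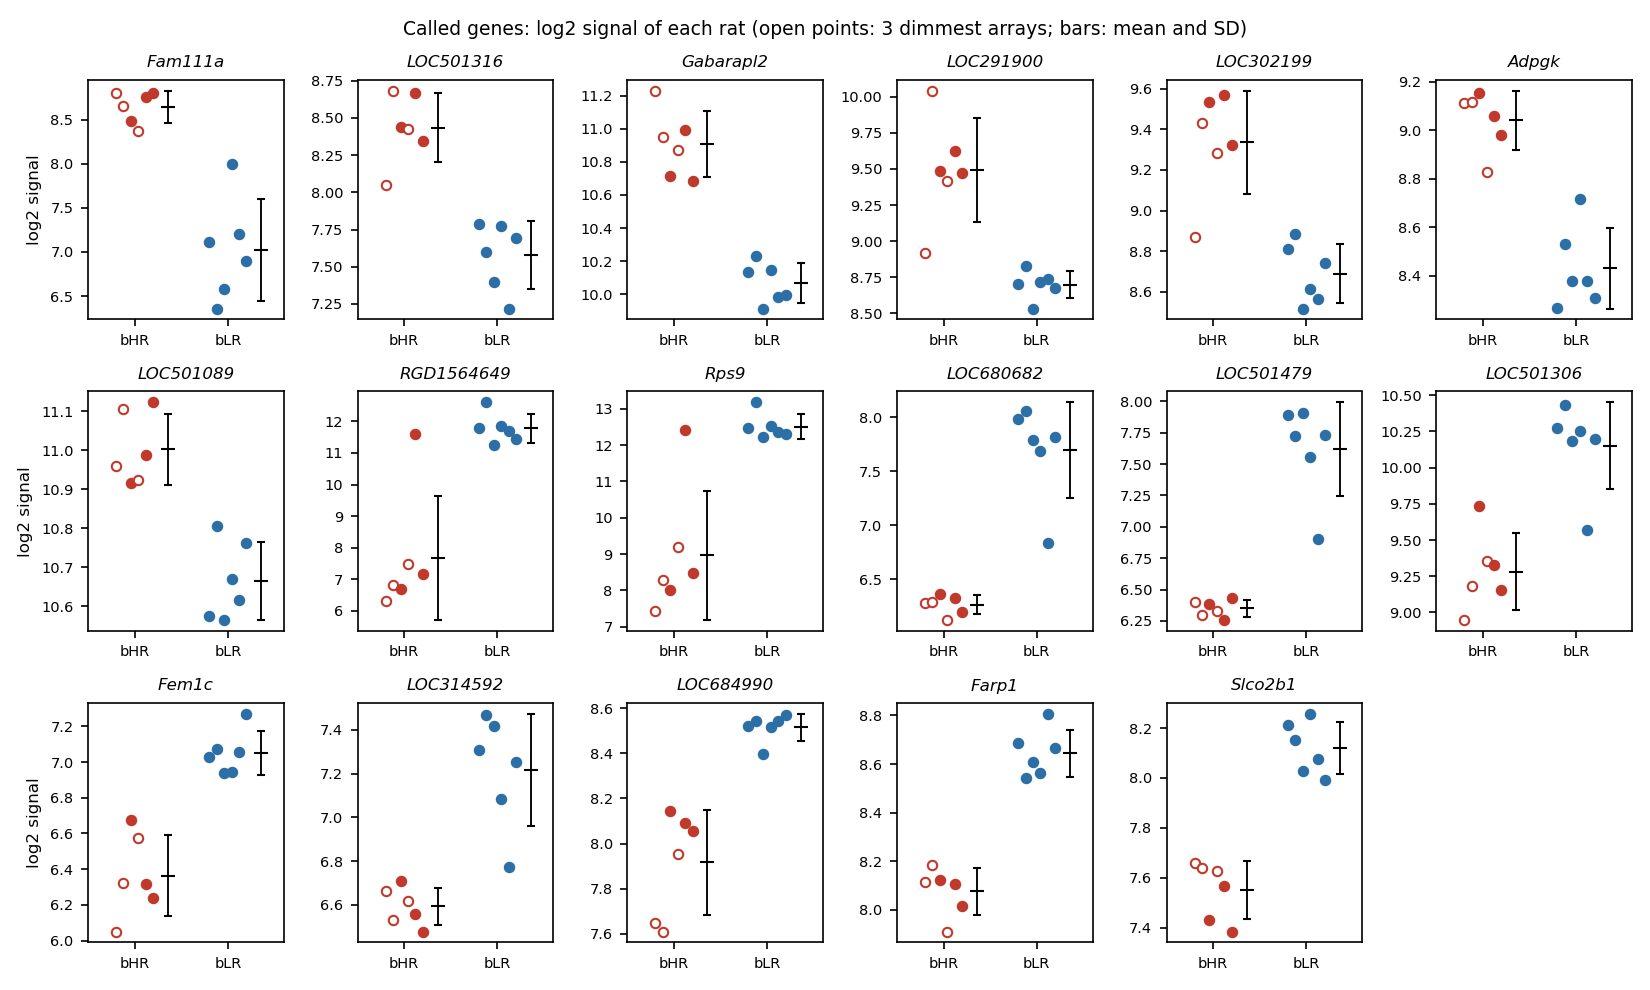
Log2 signal of each rat (y axis) for the 17 called genes named by the rule, with bHR in red and bLR in blue (n = 6 each), the 3 dimmest arrays as open points, and bars for the mean and SD. *Rps9* and RGD1564649 show 1 bHR rat at the bLR level, and LOC680682 and LOC501479 show 1 bLR rat between the lines.

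The lines differed in array brightness as well, so the comparison was repeated on the 9 brighter arrays, a choice made after seeing the data. There limma called 17 probes, 11 of them among the 20, and with brightness as a block it called 6. Within the 9, *Gabarapl2* stood at +0.74 (limma adjusted p = 0.0075), *Adpgk* at +0.65 (0.026), *Farp1* at -0.59 (0.0064), *Slco2b1* at -0.69 (0.0048) and *Fem1c* at -0.69 (0.032). *Fam111a* stood at +1.74 (limma adjusted p = 0.061), *Rps9* at -2.93 (0.36) and RGD1564649 at -3.40 (0.34), past the threshold no longer. With the block, *Gabarapl2* (+0.73), *Farp1* (-0.56), *Slco2b1* (-0.66), LOC302199, LOC680682 and LOC501479 passed, and *Adpgk* (+0.63, limma adjusted p = 0.051), *Fam111a* (+1.66, 0.053) and *Fem1c* (-0.64, 0.14) did not. The dim arrays hold bHR rats only and give no value of their own. When arrays were only centred on their medians, 6 probes passed, 0 higher and 6 lower, and without any scaling 4, 0 higher and 4 lower. Leaving out 1 rat at a time moved the count between 9 (without bLR replicate 28) and 24 (without bHR replicate 27). It fell to 12 without bHR replicate 29, 11 without bHR replicate 39, 12 without bHR replicate 47, 13 without bLR replicate 26 and 13 without bLR replicate 30.

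Of 39 gene lists, 3 passed camera with its preset correlation of 0.01, and none of these 3 calls held with an estimated correlation (adjusted p = 0.861 for each list). Cytosolic ribosomal proteins were lower in bHR, with 60 of 72 measured genes at lower values and a median of -0.089 (camera in limma, adjusted p = 0.0021, and 0.861 with the estimated correlation of 0.496). *Rps9* fell and *Rpl6* rose (+0.51 ± 0.12, with -0.01 without scaling) when adjusted over the list alone, only *Rps9* passed over all probes, and within the 9 brighter arrays *Rpl6* passed (+0.67, limma adjusted p = 0.0048) and *Rps9* did not. Oxidative phosphorylation genes were lower, 50 of 60 at lower values with a median of -0.089 (adjusted p = 0.0075), and no member passed adjusted over the list alone. Ependymal and ciliated cell markers were higher, 24 of 28 at higher values with a median of +0.10 (adjusted p = 0.0064), although their median was -0.02 with arrays centred on their medians and -0.22 without scaling, where the median of all probes was -0.22. None of them passed adjusted over the list alone, the nearest being *Drc12* (+0.19 ± 0.06) and *Tekt4*, a ciliary tektin (+0.21 ± 0.10). The 3 calls did not hold with fry either (adjusted p = 0.839 for each), and an exact permutation test of the list means gave adjusted p of 0.774 for ribosomal proteins and the ependymal list and 0.863 for oxidative phosphorylation.

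These calls depended on single rats. The mean of ribosomal genes was 11.18 in bHR replicate 27 and at least 11.86 in the other 11 rats, and without this rat the medians of the ribosomal and oxidative phosphorylation lists were +0.0126 and +0.0138 (adjusted p = 0.509). Array weights also ended both calls (adjusted p = 0.187 and 0.313). Within the 9 brighter arrays the ribosomal median was +0.0157 (adjusted p = 0.854) and that of oxidative phosphorylation +0.0358, which there passed as higher (adjusted p = 0.035), and with the block neither passed. The ependymal call was lost without bHR replicate 33 (median +0.0583, adjusted p = 0.33), bHR replicate 47 (+0.0676, 0.22) or bLR replicate 28 (+0.0923, 0.072), and within the 9 brighter arrays the median was +0.14 (adjusted p = 6.0e-05), while the list mean differed by +0.17 ± 0.13 (SE) there. Without bLR replicate 28 camera called 0 lists (8 at an unadjusted p under 0.05), and without bLR replicate 30, 42 or 46 it called 5. On the 9 brighter arrays 9 lists passed with the preset correlation, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). Among the 9 were the synaptic vesicle and postsynaptic density list (-0.135), astrocytes (-0.0925), choroid plexus (+0.199), interferon response (+0.0536), glutathione and xenobiotic metabolism (+0.0547), glutamate receptors and transport (-0.0777) and immediate early genes (-0.0605).

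**Figure D3:**
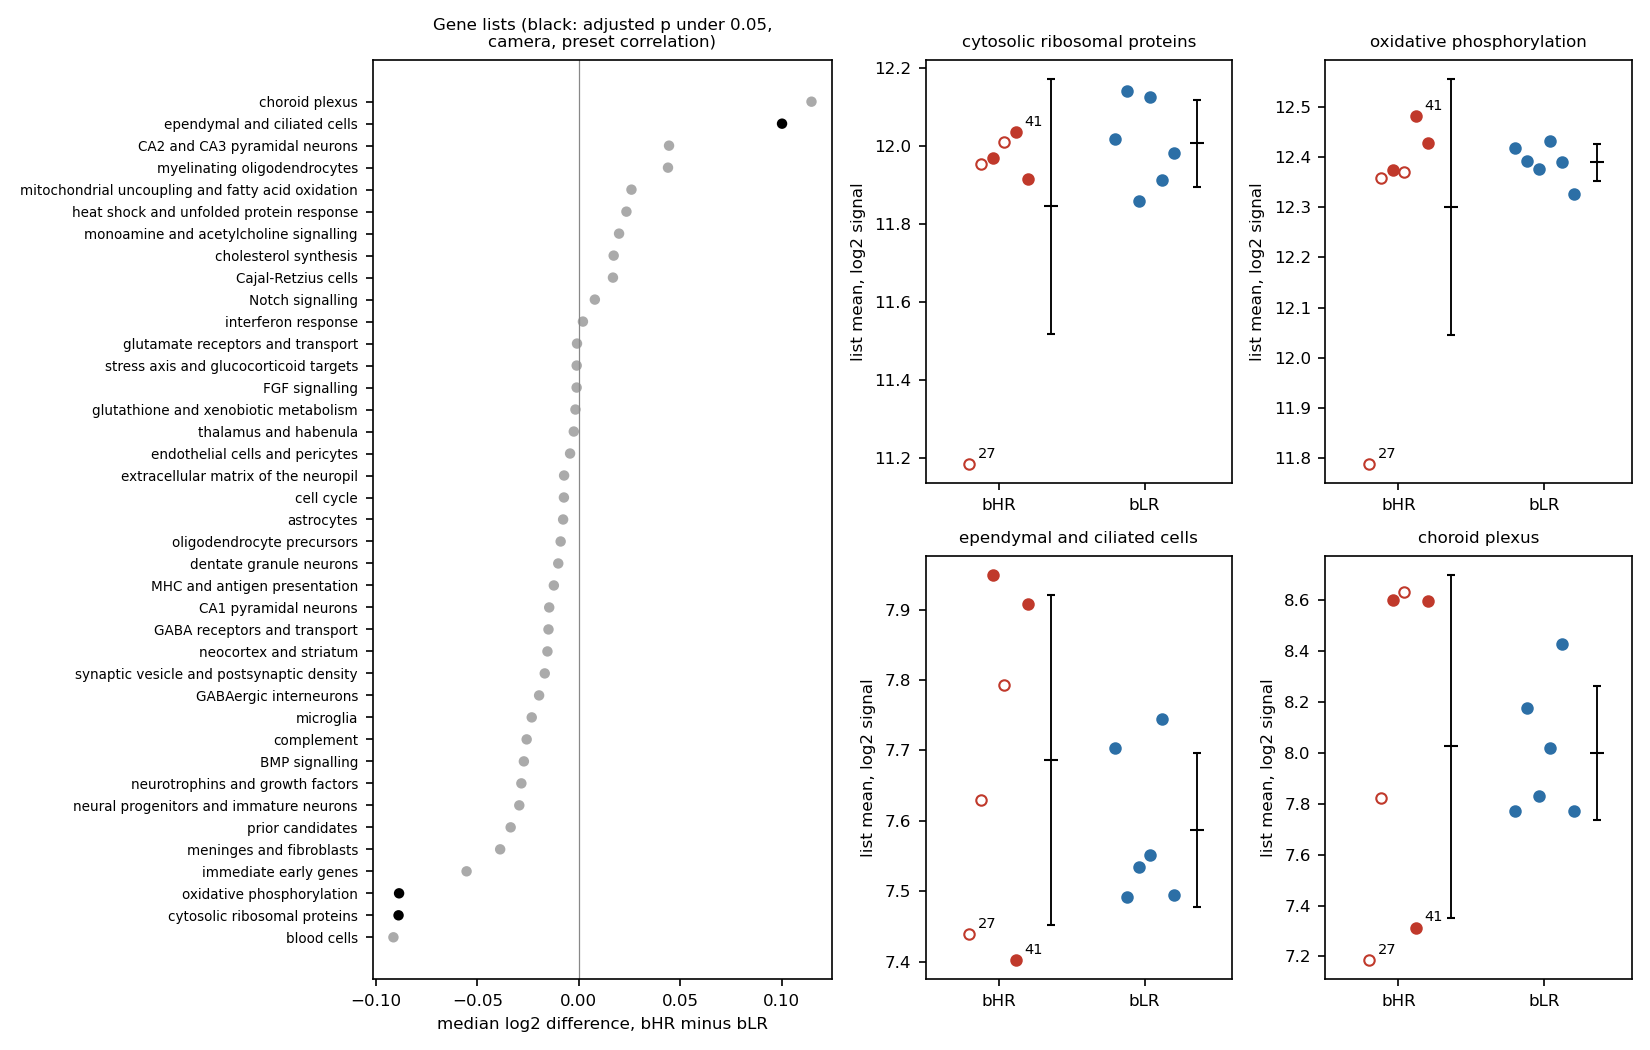
Left, median log2 difference (bHR minus bLR) of the 39 lists, black where camera with its preset correlation gave an adjusted p under 0.05. Right, mean log2 signal of 4 lists in each rat (n = 6 per line, open points for the 3 dimmest arrays, bars for mean and SD), where bHR replicate 27 is lowest for ribosomal and oxidative phosphorylation genes and replicates 27 and 41 are lowest for choroid plexus genes.

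Markers of hippocampal neurons did not pass camera. The medians were -0.0102 for dentate granule neurons, -0.0146 for CA1 pyramidal neurons, +0.0445 for CA2 and CA3 pyramidal neurons, -0.0196 for GABAergic interneurons, +0.0168 for Cajal-Retzius cells and -0.0294 for progenitors and immature neurons. Proliferation genes had a median of -0.0074. Among glia, the medians were -0.0078 for astrocytes, -0.0090 for oligodendrocyte precursors, +0.0440 for myelinating oligodendrocytes and -0.0232 for microglia. Of 27 myelinating oligodendrocyte genes, none passed over all probes. Adjusted over the list alone, *Cnp*, a myelin enzyme, rose (+0.23 ± 0.06, with -0.29 without scaling and -0.10 with median centring) and *Opalin*, a myelin membrane protein, fell (-0.45 ± 0.13). *Sox9*, a transcription factor of astrocytes, fell by the same adjustment at one probe (-0.21 ± 0.06), and its other probe gave -0.00.

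Vascular and border tissues did not pass either, with medians of -0.0043 for endothelial cells and pericytes, -0.0388 for meninges and fibroblasts, -0.0915 for blood cells (adjusted p = 0.062) and +0.115 for choroid plexus (adjusted p = 0.34). Adjusted over the list alone, the efflux transporter *Abcg2* fell (-0.50 ± 0.12) and the collagen *Col3a1* rose (+0.97 ± 0.23), and neither passed over all probes. Tissue next to the hippocampus was represented by thalamus and habenula (median -0.0025) and by neocortex and striatum (-0.0155). In the former the glutamate transporter *Slc17a6* rose when adjusted over the list alone (+0.33 ± 0.08), with -0.20 without scaling and -0.00 with median centring. Choroid plexus transcripts differed between rats of 1 line: *Ttr*, the transthyretin that choroid plexus secretes, read 7.98 in bHR replicate 27 and 9.22 in replicate 41, against 13.4 to 15.3 in the other 10 rats.

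Signalling and metabolic lists gave medians close to 0, and none of those named here passed camera. They were -0.0271 for BMP, -0.0011 for FGF and +0.0079 for Notch signalling, -0.0257 for complement, -0.0123 for antigen presentation, +0.0020 for interferon response and -0.0011 for the stress axis and glucocorticoid targets. Neurotransmission lists gave -0.0009 for glutamate, -0.0150 for GABA and +0.0198 for monoamines and acetylcholine, with -0.0284 for neurotrophins, -0.0554 for immediate early genes and -0.0168 for synaptic vesicle and postsynaptic proteins. The neuropil matrix list gave -0.0073, heat shock and unfolded protein response +0.0235, cholesterol synthesis +0.0172, glutathione and xenobiotic metabolism -0.0017, and mitochondrial uncoupling and fatty acid oxidation +0.0259. Median, mean and camera differed in sign for the GABA, glutamate, thalamus, glutathione, cell cycle, FGF and Cajal-Retzius lists.

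In the GABA list *Gabarapl2* rose and the other 32 genes did not pass. Single members passed over the list alone, and not over all probes, for 3 more genes: *Bmp4* (BMP signalling and oligodendrocyte precursors), *Cntf*, the ciliary neurotrophic factor (+0.22 ± 0.05, with -0.23 without scaling and -0.03 with median centring), and *Ephx2*, the soluble epoxide hydrolase (+1.82 ± 0.36, limma adjusted p over all probes = 0.11). For *Ephx2*, bLR replicates 26 and 46 read 9.19 and 9.19, near the bHR mean of 9.71, and the other 4 bLR rats read 7.17 to 7.32.

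Genes named in earlier work on these lines were examined one by one, and 19 were measured. Because some were chosen on these samples, their list is not independent evidence of direction. *Bmp4*, a growth factor of the TGF-beta family, averaged 7.28 ± 0.38 (SD, n = 6) in bHR and 8.01 ± 0.20 in bLR, a difference of -0.73 ± 0.15 (SE). It was the only one of the 19 to pass adjusted over the list alone (0.0045), and it did not pass over all probes (limma adjusted p = 0.13; exact permutation p = 0.0043). *Ucp2*, a mitochondrial carrier, differed by +0.27 ± 0.08 (limma adjusted p = 0.62; exact permutation p = 0.022), with -0.25 without scaling and -0.05 with median centring. None of the others passed: *C1qa* -0.16, *Tmem144* -0.16, *Fn3k* -0.15, *Htr1a* -0.09, *Bdnf* -0.07, *Timm10b* -0.06, *Trhr* -0.06, *Slc19a3* -0.03, *Drd2* -0.03, *Acss2* -0.01, *Nr3c2* +0.01, *Mki67* +0.02, *Nr3c1* +0.03, *Crhr1* +0.03, *Mfge8* +0.04, *Fgf2* +0.04 and *Pex11a* +0.04. The list as a whole had a median of -0.03 and did not pass (adjusted p = 0.41).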

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

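The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the rats, which were set before, and the test of rat 41's label was revised 2 times after earlier results. A rat was singled out where its gap to the nearest rat of its line exceeded the critical share of the line's range, in 180 groups of 6 values. Chance singles out about 1 in 20 groups, and there were 20, of which 6 concern bHR replicate 27.

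Other splits of the 12 rats bear on the counts. The lines gave 20 called probes, and 2 of 100 splits gave as many, the lines included. Chance is thus unlikely for this count but not excluded, since a mixed split equalled the lines. The other split put bHR replicates 27, 29 and 41 with bLR replicates 26, 30 and 46, and its 20 probes were the highest of the other splits. For gene lists chance cannot be excluded either, and there the count was common. The lines gave 3 called lists, 85 of 100 splits gave as many, and the highest of the others gave 15. Such counts point to a structure of the samples or to a preset correlation (0.01) below the estimated ones (0.496, 0.426 and 0.408 for the called lists), and which of these was not tested.

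At the step, bHR replicate 41 stood out at 11.59 for RGD1564649 (the other bHR rats 6.29 to 7.47) and at 12.40 for *Rps9* (7.42 to 9.20). Dim arrays are argued against, since the brighter bHR arrays other than replicate 41 averaged -3.576 from the bLR mean on the log2 scale at the probe with the smallest of 3 shifts. A mislabelled bLR rat is argued against as well: of 15 probes of other genes called without replicate 41, 13 (86.7%) put it beyond every bLR rat on the bHR side, against 22.2% to 42.9% for each bLR rat left out and placed in the same way. The first version of this test used the 17 probes called with this rat counted as bHR, a circular choice, and gave 17 of 17, and the second asked which line mean was nearer and left the label open, with 12 of 15 nearer to the other bHR rats and 3, for Crabp1_mapped, LOC499295 and *Ankrd26*, nearer to bLR. A sequence variant under the probes and a difference in transcript level cannot be told apart, because the second *Rps9* probe also gave -2.99 ± 0.505 (SE) and probe positions were not used here.

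In bLR replicate 28, *Rps9* read 13.18 (the other bLR rats 12.24 to 12.52).

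For the ribosomal and oxidative phosphorylation lists, bHR replicate 27 stood out with means of 11.18 (the others of its line 11.92 to 12.04) and 11.79 (12.36 to 12.48). Both lists lose their call without this array, while 20 of the 22 calls in the other leave-one-out fits remained, so this single array may account for the pattern. Dim arrays as a class are argued against: the other 2 dim arrays differed from the brighter bHR arrays by -0.0233 ± 0.0344 (SE), against -0.721 for replicate 27. A difference of the reported size in every bHR rat is argued against as well, since without replicate 27 the mean over both lists differed between the lines by -0.0099 ± 0.0339 (SE), against -0.129 with it. A smaller difference between the lines, and what sets this rat apart, stay open.

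The same rat had the lowest mean correlation with the other arrays, 0.9866 (0.992 to 0.994 in the other bHR rats). It was also singled out for *Acss2* at 10.15 (9.61 to 9.73), *Timm10b* at 10.01 (10.61 to 10.94) and the microglia list at 7.73 (7.87 to 7.94).

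In bLR replicate 42, LOC680682 read 6.83 (7.69 to 8.06 in the other bLR rats), LOC501479 6.91 (7.56 to 7.91) and LOC501306 9.57 (10.18 to 10.43). The BMP signalling list stood at 8.12 there (8.03 to 8.05) and the list of meninges and fibroblasts at 8.92 (8.64 to 8.73). In bLR replicate 30, LOC684990 read 8.40 (8.52 to 8.57), myelinating oligodendrocyte genes 9.31 (8.98 to 9.09) and the thalamus and habenula list 7.13 (7.18 to 7.21). The neocortex and striatum list read 8.43 in bLR replicate 28 (8.52 to 8.57), *Opalin* 7.04 in bHR replicate 33 (6.64 to 6.75) and *Nr3c2* 7.50 in bHR replicate 47 (7.81 to 7.99).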

How the results depend on the processing

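The values on the 9 brighter arrays, with brightness as a block or with the mean log2 raw signal as a covariate, estimated correlation on the brighter arrays included, were chosen after seeing the data, and a list or gene that passed neither before nor after a change is counted as the same whatever its sign. The direction of a list is that of camera, relative to the other genes. Over 49 genes, 1164 values gave 995 the same, 131 weaker, 37 stronger and 1 reversed, and over 39 lists, 1090 values gave 1001, 21, 49 and 19. *Slco2b1* and LOC501479 passed in all 23 settings, and 9 genes passed in each of the 12 fits that leave out a rat: *Adpgk*, *Fam111a*, *Farp1*, *Fem1c*, *Gabarapl2*, LOC501316, LOC501479, LOC680682 and *Slco2b1*. The 20 called probes became 6 with median centring, 4 with no scaling between arrays, 6 with the brightness block, 4 with the brightness covariate and 9 at an adjusted p of 0.01, and 9 to 24 on leaving out a rat. The other settings gave 17 to 30. The 3 called lists became 20 with median centring (all lower), 8 with no scaling, 9 on the brighter arrays (0 there with an estimated correlation), 8 with the block, 7 with the covariate, 0 with an estimated correlation, 0 with fry and 0 by exact permutation. At an unadjusted p under 0.05 the last 3 tests gave 1, 1 and 2 lists. Leaving out a rat gave 0 to 5 called lists. With median centring camera turned from higher to lower for the cell cycle (median -0.124), glutamate (-0.243) and glutathione (-0.230) lists, whose medians were negative before, and for cholesterol synthesis (-0.261), heat shock (-0.239) and mitochondrial uncoupling (-0.233). With no scaling, where the median of all probes shifted by -0.216, LOC501089 (-0.19) turned negative and camera turned lower for the glutamate list (-0.442). The ribosomal list ranged from -0.123 to +0.0126 on leaving out a rat and oxidative phosphorylation from -0.133 to +0.0138, both highest without bHR replicate 27. The ribosomal list turned to +0.0157 on the brighter arrays and +0.0159 with the block, and oxidative phosphorylation to +0.0358 and +0.0352, and to +0.0317 with the covariate. Camera also turned lower for glutamate genes, with medians of -0.0777, -0.0752 and -0.0802 on the brighter arrays, with the block and with the covariate. The ependymal median was -0.0223 with median centring and -0.221 with no scaling, where camera still placed the list above other genes. For leaving out a rat, fewer samples may explain part of the loss, which was not tested. Median centring and no scaling keep the narrower signal range of the 3 dimmest arrays, all bHR. Their ratio of the 95th to the 5th percentile was 31.1 to 33.1, against 52.4 to 67.2 on the other 9. Bright probes therefore read lower in bHR in these settings, and how much of the changes there this explains was not tested. For the remaining changes the cause was not tested either. A beadchip block was not run, because chip identifiers were not used here. No paired analysis was possible because the lines share no rat numbers. Low signals limit LOC680682, LOC501479, *Fem1c* and LOC314592 in bHR, where they lie below the median of all probes.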

Other observations

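The tests in this part were chosen after the results were seen, except that on neighbouring genes, which was set before, and the tests of dim arrays for the ependymal list and of steps between rats were each revised once after a first result.

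Choroid plexus transcripts varied widely between rats of 1 line. *Ttr* read 7.98 and 9.22 in bHR replicates 27 and 41 and at least 13.4 in the other rats, and *Sostdc1*, a secreted inhibitor of BMP and Wnt signalling, read 6.64 and 6.74 there and at least 8.99 elsewhere. The choroid plexus list mean differed between the lines by +0.03 (exact permutation p = 0.94), with an SD of 0.67 in bHR and 0.26 in bLR (n = 6 each). Over the 12 rats the ependymal list mean went with the choroid plexus list mean (Pearson's r = 0.843, permutation p = 0.00064; Spearman's rho = 0.776, permutation p = 0.0042), and r was 0.824 without the 2 rats farthest from the median choroid plexus value. On the 9 brighter arrays r was 0.834, within bHR 0.966 and within bLR 0.370. This was the only relation between lists computed.

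The higher ependymal list in bHR could come from more choroid plexus and ventricular lining in those samples, or from their dim arrays. With the choroid plexus list mean as a covariate, 91.7% of the ependymal difference was left (+0.09 ± 0.05, SE, from +0.10 ± 0.11), and on the 9 brighter arrays the difference was +0.1661 ± 0.132 (SE). The latter test was first run with camera, whose preset correlation gave an adjusted p of 6.0e-05 there, and was replaced because that p leaves out the spread of the list mean between rats. Each of these differences lies within 2 of its standard errors, so these explanations and a difference between the lines cannot be told apart.

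Signals that fall into separate levels between rats, as with *Rps9*, were sought without using the lines: 41 probes of 38 genes had a gap of over 0.75 on the log2 scale with at least 2 rats on each side. Of these, 5 probes of 4 genes (*Rps9*, RGD1564649, LOC680682 and *Fam111a*, all named above) put at most 1 rat on the wrong side of the lines. Others divided the lines less fully: *Dynlt3*, a dynein light chain, read 11.8 to 12.8 in 3 bHR rats and 7.95 to 9.60 in the other 9 rats. *Rpl30* read 11.02 to 11.92 in 2 bHR and 5 bLR rats and 6.00 to 8.79 in the rest, and *Bnip3*, of mitochondrial turnover, 11.5 to 13.0 in 4 bHR and 2 bLR rats and 8.08 to 8.86 in the rest. These genes were chosen after their values were seen. A hypothesis is that such steps mark alleles whose frequency differs between the lines. Because called probes prompted the search, the test was revised to leave out all 5 of them, and on the other 36 probes 1 of the 462 splits of the 12 rats, the lines themselves, separated the steps this well (summed difference in the share of high rats 12.83, highest other split 10.83). With all 41 probes, as first run, the values were 17.0 and 14.7, again 1 split. Without the called probes and the 5 that were low in bHR replicates 27 and 41 alone, *Ttr* and *Sostdc1* among them, the lines still ranked first, by a narrow margin (11.17 and 10.83). The hypothesis predicts this, but shared parentage within a line would give the same result. The sum counts probes and not genes: *Ifi27* and RGD1564247 entered with more than 1 probe, and *Bnip3* and *Bnip3-ps1* were high in the same rats. F5_mapped, also lowest in bHR replicates 27 and 41, stayed in. The narrow margin was not recomputed with 1 probe per gene. Array brightness was not separated from the lines here. *Plekhf2* read 8.04 to 9.02 on the 3 dimmest arrays, all bHR, and 6.23 to 6.53 on the other 9, while *Dynlt3* was high in bHR replicates 27, 29 and 47. Whether a step lies in the transcript or under the probe was not tested.

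Stretches of chromosome that differ between the lines could make neighbouring genes differ together. Over 8872 pairs of neighbouring genes of the GRCr8 assembly that do not overlap or share a name stem, the rank correlation of the absolute limma statistic was 0.0188. As high a value came from 11 of 100 splits of the rats, the lines included, with 0.0301 the highest of the others. No such clustering was thus shown beyond chance among the 9633 genes placed. Genes whose symbol did not match the assembly's table, or that lay below the median signal, could not enter. The test therefore does not bear on stretches that hold such genes.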
